A study of Bos taurus with 16 samples.

How the data were processed

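RNA from needle biopsies of the mammary gland, stored in a stabilising solution and frozen, was extracted with a column kit, turned into biotin-labelled cRNA and hybridised to Affymetrix arrays, per the labels. The labels describe 16 heifers and give 1 array each. The p-values thus rest on the spread between heifers, from which variation of biopsy, RNA and array cannot be separated. The values used are those the authors deposited, on the log2 scale, with GCOS and RMA named in the submitters' processing notes, without versions. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. The log base is not stated in the sources used here; values between 2.7 and 12.7 on every array are those of RMA on a log2 scale, and all differences are given as log2 on that reading. The chip definition, any filter and the scan dates are not given in the sources used here. No scanner files were used, so background and detection per probe set were not assessed, and RMA values of dim probe sets understate differences, as do those near the top of the scale.

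Of 26773 probe sets, the annotation of the array gives 1 gene symbol to 18790, covering 18435 genes, several symbols to 385 and none to 7598, which are called unnamed here. Symbols were set against the RefSeq gene table of assembly ARS-UCD2.0, used for names alone: 18003 gene IDs matched with no change of symbol, and 21 symbols without such a match were updated through a synonym, TCEB2 to ELOB among them. There were 297 probe sets that share all 16 values with another probe set, which leaves 26590 distinct sets of values. Probe sets with several symbols were tested but not named. No coordinates are given, since the build behind the array is not given in the sources used here. No pair of arrays held identical values, and the correlation between arrays ran from 0.842 to 0.992.

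CON was compared with NOCON, group labels coming from the sample titles. The test was limma (lmFit and eBayes with default settings, version 3.58.1 in R 4.3.3) on the deposited values without covariates, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Signed differences are CON minus NOCON. Exact two-sided permutation tests over all 12870 regroupings were run for each probe set and for measures per array. Gene lists were tested with limma's camera at its preset correlation of 0.01, on 1 value per gene, the probe set with the highest mean, with adjustment over all 29 lists; a list needed 3 measured members. Beside it camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run. Adjusted p-values of single list members are over 18435 genes.

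The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The pathway lists were milk proteins, fatty acid and triglyceride synthesis, cholesterol synthesis, lactose synthesis and glucose transport, amino acid transport, calcium and ion transport, hormone and insulin signalling, involution and tissue remodelling, acute phase and innate defence, interferon response, MHC class II and antigen presentation, cell cycle, unfolded protein response, immediate early genes, heat shock proteins, DNA methylation and histone modification, oxidative phosphorylation and cytosolic ribosomal proteins. The cell type lists were luminal epithelium, myoepithelium and smooth muscle, adipocytes, fibroblasts and matrix, endothelium, T and NK cells, B and plasma cells, macrophages and dendritic cells, neutrophils, erythrocytes and skeletal muscle. Named are all genes with 1 symbol that pass, filled up, when fewer than 20 pass, to 12 per direction by the smallest unadjusted p under 0.05 with a log2 difference of at least 0.3. To these the rule adds the 4 members with the smallest p of each called list, the 2 of each other list, and CSN1S1, CSN2, CSN3, LALBA, PAEP, LTF, FASN, SCD, IGF1R, PRLR and ESR1. One gene of the ranking is not reported here. Where a gene has several probe sets, the ranking takes the one with the smallest p and the lists and the genes fixed by name take the brightest.

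Alternatives were a filter that keeps the 60% of probe sets with the highest mean, eBayes with trend and robust settings, array weights, median centring, a further quantile normalization, the replicate number as a block, the first principal component as a covariate, each array left out in turn, an adjusted p of 0.10, the exact test, and for lists also the mean of all probe sets of a gene. A covariate from the 3' and 5' signals of control probe sets was not run, because no probe set in the table used here carries the maker's control prefix; RNA integrity was therefore not measured. Added after seeing the data were fits without the arrays whose median correlation lies more than 5 scaled median absolute deviations below the median of all arrays (CON 2, CON 6, CON 7, NOCON 1 and NOCON 5), a count with identical probe sets taken once, and a list of mitochondrial ribosomal proteins. Median centring and quantile normalization shifted the median difference over all probe sets from 0.01 to -0.02 and -0.01.

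The procedure was tested on simulated data with 26773 probe sets and 8 arrays per group. It recovered 55% of 100 probe sets changed by 0.5 on the log2 scale and 89% of 100 changed by 1, with 6 false among 150 calls. A simulated list lowered by 0.5 passed with camera (adjusted p = 1.28e-11) and 0 of 28 other lists did. Simulated genes were drawn independently, so this says nothing about lists whose genes vary together.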

Results

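Gene expression was measured in mammary gland biopsies of 16 Parda de Montaña heifers, a Spanish mountain breed of cattle, collected when the first lactation ended. From birth to 6 months of age, 8 heifers received a starter concentrate on top of their dams' milk (CON) and the other 8 had dam's milk only (NOCON). All of them suckled for 30 min at a time. From 6 to 15 months, the heifers of the study were also split between a ration of 67% forage and 33% concentrate and a ration of 87% forage and 13% concentrate, but the labels do not say which heifer had which ration, so this factor was not compared. Each heifer gave 1 array with 26773 probe sets. Arrays are named below by group and replicate number. The median expression of an array lay between 4.25 (CON 8) and 4.57 (CON 7) on the log2 scale, and the highest value on any array was 12.66. Arrays carry no read depth, and their number, 8 per group, limits the precision.

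The comparison of CON with NOCON asks whether feeding before weaning left a trace in the mammary transcriptome at the end of the first lactation. ELOB, which encodes elongin B, a subunit of a transcription elongation complex and of cullin-based ubiquitin ligases, was 1.45-fold lower in CON. Its expression was 10.74 ± 0.10 (SD, n = 8) in CON and 11.28 ± 0.10 (SD, n = 8) in NOCON, a log2 difference of -0.53 (SE 0.06, adjusted p = 0.000743). A second probe set (12752669), listed under the older symbol TCEB2 and assigned to ELOB through that synonym, gave the same log2 difference of -0.53 at a lower level, 9.51 ± 0.14 in CON and 10.04 ± 0.19 in NOCON (adjusted p = 0.0144). NFU1, which encodes a carrier protein for iron-sulfur clusters in mitochondria, was 1.74-fold lower in CON, at 7.05 ± 0.22 against 7.86 ± 0.19 (SD, n = 8 each; log2 difference -0.80, SE 0.10, adjusted p = 0.00134).

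The remaining differences past an adjusted p of 0.05 came from probe sets that the annotation used here does not name. Probe set 12910891 was higher in CON, at 11.64 ± 0.16 against 10.93 ± 0.18 (SD, n = 8 each; log2 difference 0.70, SE 0.08, adjusted p = 0.000743), and 9 probe sets in all carried these same values on every array. Probe set 12835619 was also higher in CON, at 4.70 ± 0.32 against 3.93 ± 0.14 (log2 difference 0.77, SE 0.12, adjusted p = 0.0134). Probe set 12811225, identical in its values to others so that 3 probe sets share them, was lower in CON, at 3.79 ± 0.15 against 4.52 ± 0.28 (log2 difference -0.73, SE 0.11, adjusted p = 0.00881). The levels of the last 2 lie near the array medians, where signals are dim. In total, 16 of 26773 probe sets passed with limma, 10 higher and 6 lower in CON, and these held 6 distinct sets of values, 2 higher and 4 lower.

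For all 6, the lowest array of one group lay above the highest array of the other, and the exact permutation p was 0.000155, the smallest that the 12870 regroupings can give (two-sided). Complete separation of the groups was found for 37 distinct probe sets, against 4.13 that chance gives on average over regroupings. Single regroupings spread widely around this average, and the highest of those drawn gave 70. Because of the smallest possible p, the exact test passed no probe set after adjustment (lowest adjusted exact p 0.0885), while 2794 probe sets had an exact p under 0.05 before it and 2320 an unadjusted limma p under 0.05, 955 of them higher and 1365 lower in CON. Leaving out any 1 array gave between 16 and 20 probe sets, and ELOB and NFU1 passed in each of these 16 fits.

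**Figure D1:**
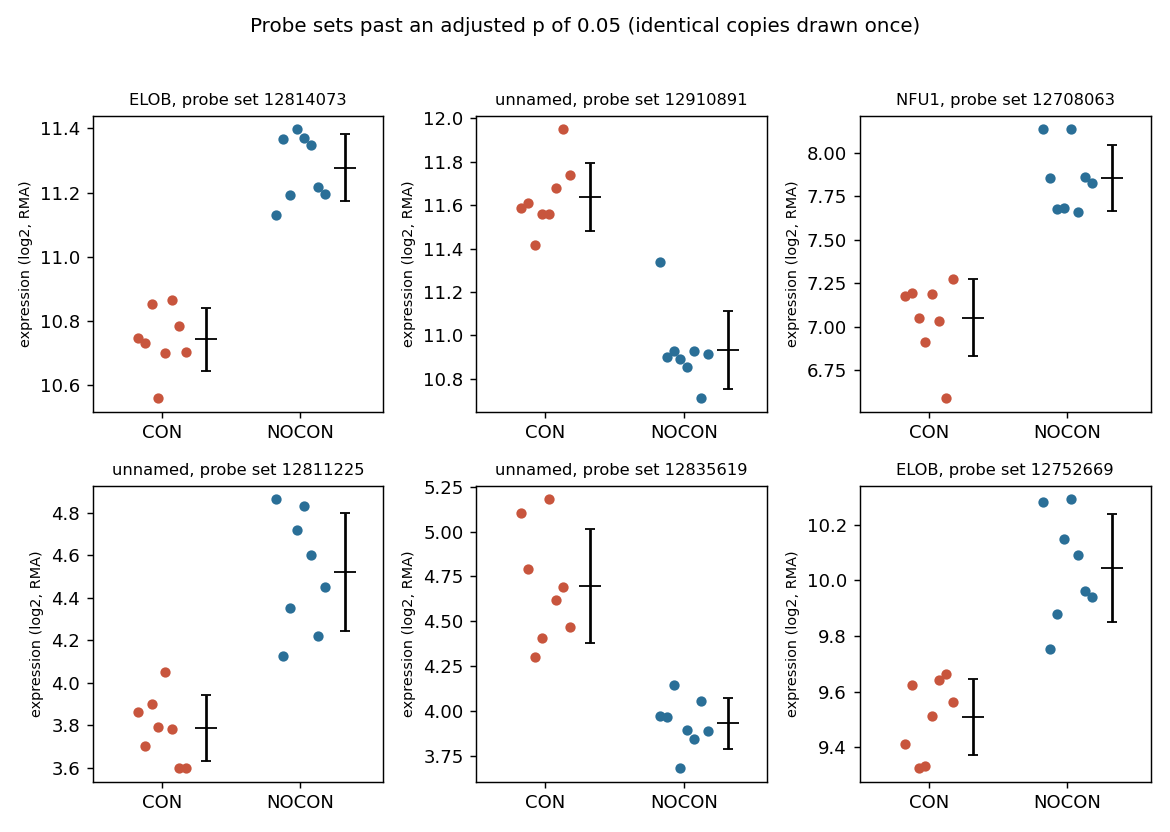
Expression (log2, RMA) of the 6 distinct probe sets past an adjusted p of 0.05, with 1 point per heifer for CON (red) and NOCON (blue) and, beside the points, the group mean with its SD (n = 8 each). The groups do not overlap in any panel; the closest approach is in probe set 12811225, where CON 5 lies at 4.05 and NOCON 2 at 4.13. The vertical axes do not start at 0 and differ between panels.

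Since only 2 named genes passed, the genes with the smallest p in each direction and a log2 difference of at least 0.3 were listed as a ranking, not as calls. Among those with higher means in CON were the microRNA genes MIR143 (log2 difference 0.99, SE 0.20, adjusted p = 0.0971) and MIR296 (1.24, SE 0.34, adjusted p = 0.373), for which the annotation names no mature arm, and MIR2284G (0.33, adjusted p = 0.383). MIR296 was highest in CON 7 (8.03) and CON 2 (7.39). Without the low-correlation arrays it differed by 0.68, while MIR143 differed by 0.99 and MIR2284G by 0.32. ANKRD26, an ankyrin repeat gene, stood at 4.80 ± 0.21 against 4.33 ± 0.17 (log2 difference 0.47, adjusted p = 0.0971). The list also held the receptor genes TACR1 (0.50), GPR39 (0.33) and OR2A14B (0.35), the melanocortin receptor accessory protein MRAP2 (0.48), the transporter SLC6A16 (0.37), the mitochondrial ribosome recycling factor MRRF (0.40) and LOC782989 (0.48), with adjusted p from 0.269 to 0.383. OR2A14B (3.77 in CON against 3.43 in NOCON) and MIR2284G (3.785 against 3.45) lay below the array medians, where signals are dim. MRAP2 (4.26 against 3.78) and SLC6A16 (4.18 against 3.81) lay near or below them. Without the low-correlation arrays LOC782989 differed by 0.29, OR2A14B by 0.24, GPR39 by 0.28 and ANKRD26 by 0.39. TACR1, MRAP2, SLC6A16 and MRRF rose to 0.66, 0.56, 0.41 and 0.47. With 1 array left out, TACR1 ran from 0.38 to 0.56 and MRAP2 from 0.37 to 0.53. TACR1 was highest in CON 4 (5.68) and MRAP2 in CON 3 (4.97), arrays that both stayed in the fit without the low-correlation arrays.

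Genes with lower means in CON came closer to the threshold. CCDC124, which encodes a coiled-coil protein, stood at 6.33 ± 0.19 against 6.84 ± 0.18 (SD, n = 8 each; log2 difference -0.51, SE 0.09, adjusted p = 0.0569). The spliceosome component CWC15 (-0.35), the collectin gene CL46 (-0.56), the Polycomb protein CBX8 (-0.31), LOC788523 (-0.88) and TEX30 (-0.40) had adjusted p from 0.066 to 0.0905. In this order they differed by -0.21, -0.40, -0.36, -0.49 and -0.48 without the low-correlation arrays. CL46 (3.45 in CON against 4.01 in NOCON) and TEX30 (4.07 against 4.47) lay near or below the array medians, where signals are dim. CL46, MRPL23 and, among the genes with higher means, MRRF each had 2 probe sets, and only that with the smallest p is given. The selenoprotein of the endoplasmic reticulum SELENOK (-0.54), CDKN2AIPNL (-0.74) and the mitochondrial ribosomal proteins MRPS18C (-0.62) and MRPL23 (-0.61) shared an adjusted p of 0.0971. In this order they differed by -0.46, -0.50, -0.43 and -0.40 without the low-correlation arrays, and CCDC124 by -0.41. Leaving out 1 array moved 7 of the genes with lower means past 0.05: CCDC124 (adjusted p = 0.0205 without NOCON 2 and 0.0463 without CON 1), CL46 (0.0277 without NOCON 4 and 0.047 without NOCON 8), SELENOK (0.0311 without NOCON 4), CBX8 (0.024) and TEX30 (0.0408), both without NOCON 1, LOC788523 (0.0473 without CON 8) and CDKN2AIPNL (0.00504 without CON 7). Each of the 7 passed in only 1 or 2 of the 16 fits. Their highest adjusted p with 1 array left out ran from 0.145 (CCDC124) to 0.252 (CDKN2AIPNL).

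None of the genes of milk synthesis fixed in advance passed. The caseins CSN1S1 and CSN3 and the whey proteins LALBA and PAEP differed by -0.01 (SE 0.07), 0.05 (SE 0.06), 0.03 (SE 0.05) and -0.08 (SE 0.05) on the log2 scale, with adjusted p from 0.636 to 0.961. CSN2, which encodes beta-casein, was at 12.38 ± 0.06 in CON and 12.27 ± 0.08 in NOCON (log2 difference 0.10). Its exact permutation p was 0.0014 (two-sided), or 0.195 after adjustment over all probe sets, and its adjusted p with limma was 0.557. These transcripts lie close to the highest values on the arrays, where differences can be compressed. The lipogenic enzymes FASN and SCD differed by 0.01 (SE 0.07) and 0.01 (SE 0.09), and median centring turned both signs. The iron-binding milk protein LTF differed by -0.08 (SE 0.43), the receptors IGF1R by -0.15 (SE 0.13) and PRLR by -0.27 (SE 0.30), and ESR1 by 0.35 (SE 0.25), with adjusted p from 0.656 to 0.956. Without CON 7, where PRLR lay at 6.15, the difference of PRLR was 0.01 and that of IGF1R -0.08, and without CON 8 that of ESR1 was 0.16.

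Groups of genes were compared with 29 lists, 18 of pathways and 11 of cell types, of which 8 passed with camera at its preset correlation, 7 lower and 1 higher in CON. None of the 8 passed with an estimated correlation, where no list had an unadjusted p under 0.05 either, and none with fry, where 1 had. Across the 646 list members, 58 had an unadjusted limma p under 0.05 and 0 passed over all 18435 genes. Adjusted over the list alone, 1 member passed in each of 2 lists and none in the other 27. Of the 8 lists, 1 was called without CON 7, the array with the narrowest interquartile range (1.49). Without NOCON 1, 3 were called, and 5 each without CON 2, without CON 5 and without NOCON 5. None was called without the 5 arrays of low correlation (CON 2, CON 6, CON 7, NOCON 1 and NOCON 5), a fit chosen after the data were seen.

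The cholesterol synthesis list had 16 of 17 members with lower means in CON (median log2 difference -0.32, camera adjusted p = 0.0062; adjusted p = 0.735 with an estimated correlation). The sterol reductase TM7SF2 differed by -0.60 (SE 0.23), the sterol isomerase EBP by -0.38 (SE 0.18), the sterol oxidase MSMO1 by -0.64 (SE 0.35) and SREBF2, the transcription factor that drives this pathway, by -0.18 (SE 0.10), and none of them passed. The mean of the list in CON 7 was -1.21 relative to all arrays, against 0.01 ± 0.32 in the other CON arrays. Without that array the median of the list was -0.13 (adjusted p = 0.245), and EBP and MSMO1 differed by -0.24 and -0.33. The median was -0.20 with quantile normalization (adjusted p = 0.127) and -0.0091 without the low-correlation arrays, where the test pointed up (adjusted p = 0.984).

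The unfolded protein response list, genes that act on protein folding in the endoplasmic reticulum, had 20 of 21 members with lower means in CON (median -0.22, camera adjusted p = 0.00274; adjusted p = 0.735 with an estimated correlation). The stress-induced transcription factor DDIT3 differed by -0.45 (SE 0.15), MANF by -0.59 (SE 0.27), CRELD2 by -0.29 (SE 0.13) and CHAC1 by -0.40 (SE 0.21), none past the threshold. Its mean in CON 7 was -0.96, and without that array the median was -0.08 (adjusted p = 0.156) and MANF differed by -0.38, while CHAC1 differed by -0.20 without NOCON 8. CHAC1, at 3.92 in CON against 4.32 in NOCON, lay near or below the array medians, where signals are dim. The median was -0.12 with quantile normalization (adjusted p = 0.0501) and -0.03 without the low-correlation arrays (adjusted p = 0.181). In the heat shock protein list, 12 of 15 members had lower means in CON (median -0.13, camera adjusted p = 0.0445; adjusted p = 0.759 with an estimated correlation). The co-chaperone DNAJB1, at 6.46 ± 0.29 against 6.84 ± 0.12 (SD, n = 8 each; log2 difference -0.38), was the member that passed when adjusted over the list alone (adjusted p = 0.0419 with limma). The mitochondrial chaperonins HSPD1 (-0.22) and HSPE1 (-0.15) and the small heat shock protein CRYAB (-0.45) did not pass. The mean in CON 7 was -0.77, and without it the median was -0.04 (adjusted p = 0.384) and CRYAB differed by -0.22, and without the low-correlation arrays the median was -0.05 (adjusted p = 0.36). The list was called in 9 of the 16 fits that left out 1 array, not without CON 1, 2, 4, 6 or 7 or NOCON 2 or 3 (adjusted p from 0.0527 to 0.384).

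Of the oxidative phosphorylation genes, 65 of 83 had lower means in CON (median -0.10, camera adjusted p = 0.00158; adjusted p = 0.735 with an estimated correlation). UQCRQ and NDUFA13, subunits of respiratory complexes, were at 9.76 ± 0.17 against 10.02 ± 0.13 and at 9.999 ± 0.18 against 10.27 ± 0.13 (SD, n = 8 each), and ATP5MC1 and COX7A1 differed by -0.42 (SE 0.14) and -0.33 (SE 0.11), none past the threshold. The mean in CON 7 was -0.52. Without CON 7 the median was -0.05 (adjusted p = 0.159), and without NOCON 1 the adjusted p was 0.0523. The median was -0.05 with quantile normalization (adjusted p = 0.403) and -0.0051 without the low-correlation arrays, where the test pointed up (adjusted p = 0.395). Of the cytosolic ribosomal protein genes, 46 of 65 had lower means in CON, with a smaller median of -0.05 (camera adjusted p = 0.0062; adjusted p = 0.735 with an estimated correlation). RPL22 (-0.23, SE 0.07), RPS16 (-0.26, SE 0.08), RPS7 (-0.18, SE 0.06) and RPS15 (-0.15, SE 0.05) did not pass. This was the list still called without CON 7 (adjusted p = 0.0325; range over 25 alternatives 0.000234 to 0.735), but not without CON 5 (0.0546) or NOCON 1 (0.235), and without the low-correlation arrays its median was -0.03 (adjusted p = 0.0681).

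Immediate early genes, transcription factors and regulators that respond within minutes to stimuli and handling, had lower means in CON in 17 of 24 cases (median -0.06, camera adjusted p = 0.0288; adjusted p = 0.735 with an estimated correlation). GADD45B was at 6.96 ± 0.56 against 7.63 ± 0.28 (SD, n = 8 each; log2 difference -0.67), and JUNB (-0.27), JUND (-0.14) and KLF2 (-0.20) went the same way, with none past the threshold. The mean of the list was lowest in CON 2 (-0.21), followed by CON 7 (-0.12). Its median was -0.04 without CON 2 and -0.08 without CON 7, and its adjusted p lay between 0.0504 and 0.0995 without CON 1, CON 2, CON 7, NOCON 1 or NOCON 5. The median was -0.06 without the low-correlation arrays (adjusted p = 0.427). Among luminal epithelium markers, 15 of 18 had lower means in CON (median -0.13, camera adjusted p = 0.0328; adjusted p = 0.735 with an estimated correlation). The keratin KRT18 (-0.30, SE 0.11), the tight junction protein CLDN3 (-0.23, SE 0.11), SPINT1 (-0.28, SE 0.16) and EPCAM (-0.28, SE 0.17) did not pass. The mean of these markers was -0.52 in CON 7 against 0.01 ± 0.04 in the other CON arrays and 0.05 ± 0.09 in NOCON, and without CON 7 the median was -0.08 and the difference of EPCAM -0.12. The adjusted p was 0.41 without CON 7, 0.0586 without CON 5, 0.0955 without NOCON 1, 0.0853 without NOCON 4 and 0.0883 without NOCON 5. The median was -0.08 with quantile normalization (adjusted p = 0.427) and -0.03 without the low-correlation arrays (adjusted p = 0.743).

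The interferon response list was the one with higher values in CON, in 15 of 19 members (median 0.10, camera adjusted p = 0.0456; adjusted p = 0.735 with an estimated correlation). The guanylate-binding protein GBP5 (0.18, SE 0.07), the chemokine CXCL9 (0.21, SE 0.09) and the deconjugating enzyme USP18 (0.18, SE 0.09) had higher means in CON and did not pass. Their levels lay below the array medians, where signals are dim: 4.03 in CON against 3.85 in NOCON, 3.57 against 3.36 and 3.90 against 3.72. The member with the smallest p went the other way: the exonuclease ISG20 was at 6.38 ± 0.29 in CON and 6.89 ± 0.26 in NOCON (SD, n = 8 each; log2 difference -0.50) and passed when adjusted over the list alone (adjusted p = 0.0289 with limma). The list was called in 7 of the 16 fits that left out 1 array, not without CON 2, 5, 6 or 7 or NOCON 1, 2, 5, 6 or 8 (adjusted p from 0.0733 to 0.156). Its mean was highest in CON 2 (0.47), followed by CON 7 (0.26), and its median was 0.09 both in the fit without CON 2 and in that without CON 7. Over all fits with 1 array left out the median ran from 0.08 to 0.16. Without the low-correlation arrays the median was -0.0047 and the test pointed down (adjusted p = 0.785).

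**Figure D2:**
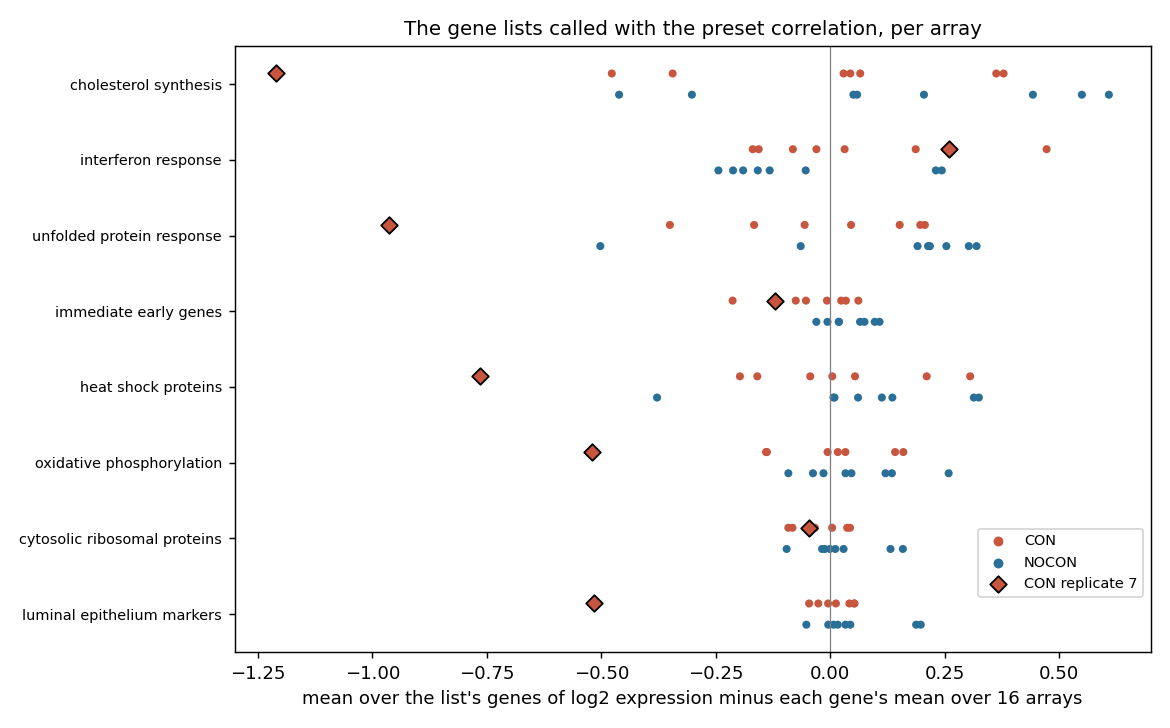
Mean of each called gene list per array, as log2 expression minus each gene's mean over the 16 arrays, with CON in red above and NOCON in blue below for each list, and CON 7 as a diamond. CON 7 is the lowest CON array in 5 of the 8 lists, at -1.21 for cholesterol synthesis and -0.52 for luminal epithelium markers; points of the groups overlap in every list.

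The other pathway lists had camera adjusted p from 0.121 to 0.931. The milk protein list had 7 of 11 members with higher means in CON (median 0.02, adjusted p = 0.404), led by CSN1S2 at 11.89 ± 0.10 against 11.78 ± 0.04 (SD, n = 8 each) and CSN2, and its median turned below 0 with median centring. Fatty acid and triglyceride synthesis had 18 of 27 members below 0 (median -0.01, adjusted p = 0.916), with THRSP at 0.06 and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, at -0.52 (SE 0.48), which were 0.03 and -0.25 without CON 7. Lactose synthesis and glucose transport had 8 of 11 below 0 (adjusted p = 0.404), and its glucose transporters went apart, SLC2A1 by -0.26 (SE 0.12) and SLC2A12 by 0.25 (SE 0.12). Amino acid transport (8 of 11 below 0, adjusted p = 0.914) held SLC6A14 at 0.12 and SLC7A5 at -0.37. Calcium and ion transport (8 of 11 below 0, adjusted p = 0.911) held the calcium sensor STIM1 at 0.24 and the zinc transporter SLC39A8 at -0.11, which was -0.02 without CON 7. With 1 array left out STIM1 ran from 0.15 to 0.35. THRSP and SLC6A14 had group means below the array medians, where signals are dim.

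In the list of growth hormone, insulin-like growth factor, prolactin and insulin signalling, 19 of 25 members had lower means in CON (median -0.14, adjusted p = 0.121; -0.06 and 0.739 without CON 7), among them the kinase AKT1 (-0.30, SE 0.12) and the cytokine signalling inhibitor SOCS1 (-0.15, SE 0.06). Involution and tissue remodelling genes had a median and a mean of -0.02 while the test pointed up (adjusted p = 0.931), with the apoptosis gene BCL2L11 at -0.11 and the protease PLAU at 0.09. Acute phase and innate defence genes were above 0 in 17 of 25 (adjusted p = 0.255), with the antimicrobial peptide LAP at 0.10 and the chemokine CXCL5 at -0.07. MHC class II and antigen presentation genes were above 0 in 12 of 19 (adjusted p = 0.255), with BOLA-DOB at 4.79 ± 0.49 against 4.46 ± 0.08 (SD, n = 8 each), a difference of 0.33 that was 0.16 without CON 7, and PSMB9 at -0.15. Cell cycle genes were above 0 in 21 of 30 (median 0.03, adjusted p = 0.187; median 0.01 without CON 7, the highest CON array), with the replication factor CDC6 at 0.13 and TK1 at 0.17. DNA methylation and histone modification genes were below 0 in 16 of 22 (median -0.06, adjusted p = 0.529; median 0.02 without CON 7), with the demethylase TET1 at 0.22 and the methyltransferase EZH2 at -0.42. None of these members passed. SOCS1, LAP, CXCL5 and CDC6 had group means below the array medians, where signals are dim.

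No cell type other than luminal epithelium was called. Adipocyte markers were below 0 in 12 of 17 (median -0.04, adjusted p = 0.341; median -0.02 without CON 7), with the adipokine CFD at 7.71 ± 0.31 against 8.22 ± 0.37 (SD, n = 8 each) and CEBPA at -0.20. T and NK cell markers were above 0 in 15 of 24 (median 0.04, adjusted p = 0.118; median 0.02 without CON 7), with ZAP70 at 0.23 and CD27 at 0.17 (0.10 without CON 7). Macrophage and dendritic cell markers were above 0 in 14 of 20 (adjusted p = 0.404), with FCGR3A at 0.21 and CD163 at 0.19. B and plasma cell markers (adjusted p = 0.931) held DERL3 at -0.13 and IGLL1 at -0.18. Neutrophil markers had a median of -0.02, a mean of 0.04 and a test that pointed up (adjusted p = 0.931), with the cathelicidins CATHL1 at 0.56 (SE 0.39) and CATHL2 at 0.44 (SE 0.40), which were 0.17 and 0.07 without CON 7. Myoepithelium and smooth muscle markers (8 of 13 above 0, adjusted p = 0.729) held KRT5 at 0.15 and CNN1 at 0.19, which were 0.28 and 0.31 without CON 7 but 0.09 and 0.02 without CON 5. Fibroblast and extracellular matrix markers (adjusted p = 0.911) held THY1 at -0.37 and COL5A2 at 0.12, and endothelium markers (adjusted p = 0.523) EGFL7 at -0.33 and CLDN5 at -0.13. Erythrocyte markers (adjusted p = 0.931) held HBQ1 at -0.14 and ALAS2 at 0.12 (0.0043 without CON 7), and skeletal muscle markers (adjusted p = 0.729) CASQ1 at 0.11 and CKM at -0.12. CD163, DERL3, CATHL1, CASQ1 and CKM had group means below the array medians, where signals are dim. Without CON 7, the medians of 8 of the 21 lists that were not called changed sign: fatty acid synthesis, amino acid transport, calcium and ion transport, involution, DNA methylation, endothelium, B and plasma cells and skeletal muscle. That of lactose synthesis and glucose transport went from -0.11 to -0.0011, that of myoepithelium from 0.05 to 0.16, that of fibroblast markers from -0.06 to -0.0022, that of antigen presentation from 0.09 to 0.06, that of macrophages from 0.03 to 0.05, that of neutrophils from -0.02 to -0.03 and that of erythrocytes from -0.01 to -0.05. The medians of the fatty acid, fibroblast, B cell and skeletal muscle lists changed sign with a further quantile normalization, and all lay within 0.07 of 0 as deposited.

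On the largest axis of variation, the arrays of the groups were not told apart, and other axes were not tested. The first principal component held 54.4% of the variance, and the scores were 10.1 ± 49.7 in CON and -10.1 ± 22.04 in NOCON (SD, n = 8 each; exact permutation p = 0.381, two-sided). CON 7 lay at 120.2 on this axis, with a median correlation of 0.866 with the other arrays and a slope of 0.756 on their mean. Lower correlations than in the rest were also found for CON 2 (0.964), CON 6 (0.971), NOCON 1 (0.953) and NOCON 5 (0.974), against at least 0.986 in the remaining arrays. The median of all values, their interquartile range and the median correlation did not differ between groups by more than the spread between arrays (exact permutation, adjusted p from 0.759 to 0.767 over these 3 measures). The deviation of each array from the others of its group was 0.166 ± 0.087 in CON and 0.110 ± 0.043 in NOCON (SD, n = 8 each; exact permutation p = 0.0836, two-sided).

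**Figure D3:**
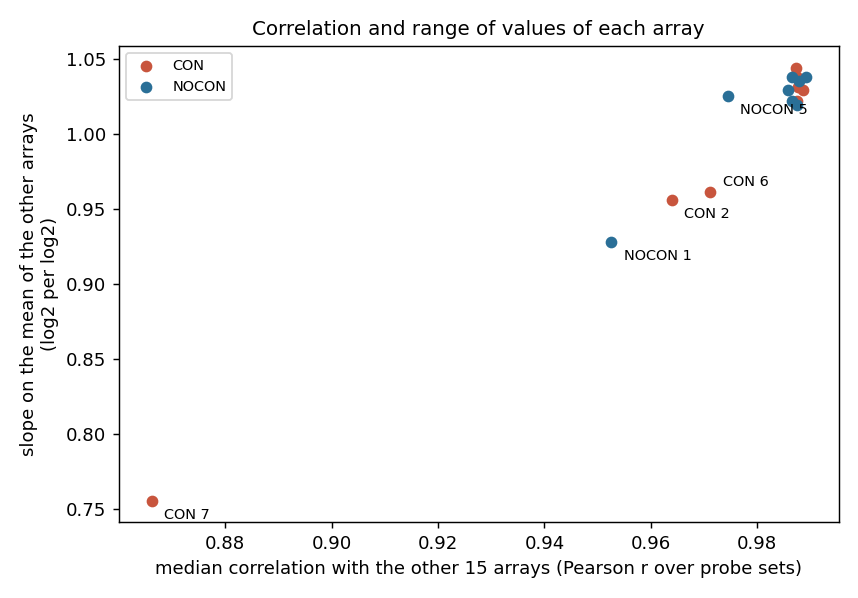
Median Pearson correlation of each array with the other arrays (horizontal axis) against its slope on their mean (vertical axis, log2 per log2), with 1 point per array for CON (red) and NOCON (blue). CON 7 stands apart at a correlation of 0.866 and a slope of 0.756. The axes do not start at 0.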

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

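The tests that leave out CON 7 or the low-correlation arrays, the count of separated probe sets as a test of batch, the resampled list members and the splits for unadjusted p-values were chosen only after the results were seen. Single arrays were compared with the other arrays of their group by the gap to the nearest array over the range of the group, in 144 groups of values, of which 31 exceeded the critical value of Dixon's test where chance gives about 7.2; 15 of the 31 concern CON 7.

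CON 7 stood apart in the median of all values (4.57, next 4.32; ratio 0.776), in its median correlation with other arrays (0.866, next 0.964; ratio 0.799), on the first principal component (120.2, next 31.98; ratio 0.605) and in its deviation from its group (0.378, next 0.156; ratio 0.843). Its list means were lowest for luminal epithelium markers (ratio 0.826), involution and tissue remodelling (0.651), fatty acid and triglyceride synthesis (0.597), oxidative phosphorylation (0.559), calcium and ion transport (0.541) and heat shock proteins (0.53), and highest for B and plasma cell markers (0.639) and skeletal muscle markers (0.603). Among named genes it was lowest for PRLR (6.15, next 7.95; ratio 0.722), CDKN2AIPNL (6.63, next 7.53; ratio 0.706) and MRPL23 (7.45, next 7.89; ratio 0.548).

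NOCON 1 stood apart in the same direction, with the lowest interquartile range (1.68, next 1.96; ratio 0.587), the lowest median correlation (0.953; ratio 0.598) and the highest first component (39.76, next -5.29; ratio 0.641). Its list means were lowest in NOCON for amino acid transport (ratio 0.69), growth hormone, prolactin and insulin signalling (0.654), involution and tissue remodelling (0.621), DNA methylation and histone modification (0.553), heat shock proteins (0.547) and the unfolded protein response (0.532). It was also lowest for LTF (7.44, next 9.58; ratio 0.714), PRLR (7.52, next 8.37; ratio 0.758) and IGF1R (6.39, next 6.74; ratio 0.531), and highest for probe set 12910891 (11.34, next 10.93; ratio 0.656). CON 4 was highest in CON for TACR1 (5.68, next 4.88; ratio 0.63) and MIR2284G (4.33, next 3.83; ratio 0.641), and NOCON 2 lowest in NOCON for CSN2 (12.08, next 12.24; ratio 0.615).

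The 6 distinct probe sets that separated the groups, ELOB and NFU1 among them, were weighed against chance, arrays of low correlation and batch. Of 100 splits of the 16 arrays drawn from 6435, 1 (the real one) passed 16 or more probe sets, and the highest other split passed 1. That makes chance unlikely for this number. Chance is not excluded, since only 100 splits were drawn and the 16 probe sets held 6 distinct sets of values. Without the 5 arrays of low correlation, 4 of the 6 still passed, and 12811225 (log2 difference -0.57) and 12835619 (0.76) lost their calls with fewer arrays at adjusted p of 0.125 and 0.181. These 5 arrays therefore do not account for ELOB or NFU1. A processing batch that followed the groups cannot be told apart from feeding, since no label gives one: 37 distinct probe sets separated the groups completely, and the highest of the other splits gave 70, a structure among arrays that the groups do not follow. An uneven split of the rations after weaning between the groups cannot be told apart either, since the labels do not give the ration of each heifer. An effect of the early feeding on ELOB and NFU1 stays open as a hypothesis.

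The 8 called gene lists were weighed against chance, against CON 7 and against the 5 arrays of low correlation. As many lists were called in 60 of the 100 splits, with 19 in the highest other split and a median of 9, so chance cannot be excluded for this number. Without CON 7, the array with the narrowest interquartile range, the medians went to 0.533 of their size (median over the lists). In the immediate early and interferon lists they went to 0.861 or more. Resampled members ranged down to 0.229 there, which leaves the part of that array open. Without the 5 arrays of low correlation the medians of the 8 lists went to 0.181. They ran from -0.0463 for interferon response to 0.91 for immediate early genes, and none of the lists was called. Most list differences thus rest on these arrays, as low quality would give. Real differences between heifers or biopsies would give the same, and RNA integrity was not measured. For the ribosomal protein list alone, the adjusted p without CON 7 was 0.0325, so that array is not its whole cause, but 28 of the 100 splits gave as small a camera p, and a biological effect of feeding on any of the lists remains untested.

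The 2320 probe sets with an unadjusted p under 0.05 were matched or exceeded in 13 of the 100 splits, the real one included, so chance cannot be excluded for that number. The highest other split gave 7470, which points to a structure among the arrays that feeding does not follow.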

How the results depend on the processing

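The fits without low-correlation arrays and the count with identical probe sets taken once were chosen only after the data were seen; the other alternatives here were planned. Against 16 probe sets, array weights gave 67 (24 higher, 43 lower), the first component as a covariate 44 (19 and 25), an adjusted p of 0.10 gave 35 (14 and 21), identical probe sets counted once 6 and the exact test 0; leaving out 1 array gave 16 to 20. The replicate block gave 4, all lower, and ended the calls of ELOB (adjusted p = 0.0791), probe sets 12910891 (0.0791) and 12835619 (0.118) and the heat shock list. After the group mean of each probe set was subtracted, same-numbered arrays correlated between -0.427 and 0.292, with 2 of 8 pairs over 0.1. On these values 1 of 8 CON arrays correlated best with its own number. The deviations from the group means, taken over all probe sets, thus gave no sign that the numbers pair heifers. A pairing or batch that touches only some genes would not show there, so it stays open. Against 8 gene lists, an estimated correlation, fry, the 60% filter, quantile normalization and the fit without low-correlation arrays gave 0, median centring 5, the first component 1, and leaving out 1 array 1 to 10. Over 24 settings, 2572 of 2645 recomputed values of 111 named probe sets kept their sign and side of the threshold, 31 newly passed, 5 no longer passed and 37 changed sign, all of these in genes that were not called. Sign changes were LALBA -0.000246, PRLR 0.00891, INSIG1 0.0243 and ALAS2 -0.0265 with array weights; FASN -0.0198 and SCD -0.0178 with median centring; FASN -0.00921 with quantile normalization; LTF 0.193, PRLR 0.0631, ALAS2 -0.0122 and the heat shock median 0.0108 with the first component; and without low-correlation arrays PRLR 0.056, INSIG1 0.0261, CRYAB 0.00387, ALAS2 -0.0474, the first component itself (-11.29) and the tests of cholesterol synthesis (median -0.00907), interferon response (-0.0047) and oxidative phosphorylation (-0.00506). The 60% filter turned the group difference of array medians to -0.0259. With 1 array left out, CSN1S1 ran from -0.0424 to 0.0345, LTF from -0.406 to 0.122, FASN from -0.0175 to 0.0512, SCD from -0.0281 to 0.0578, PRLR from -0.391 to 0.0135, ESR1 from 0.157 to 0.467, IGF1R from -0.219 to -0.0762, CSN3 from 0.0167 to 0.0771, LALBA from 0.0128 to 0.0504 and HBQ1 from -0.198 to -0.0693. Fewer arrays or fewer probe sets explain part of these shifts by construction; otherwise the cause was not tested. The covariate of 3' and 5' control signals was not run. Signal over background was not measured, which limits dim probe sets such as 12811225.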

Other observations

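The tests of mitochondrial ribosomal proteins and of RBIS were chosen only after these genes had been noticed, and the genes of single heifers were picked after their values were seen. Some immune genes were high in single heifers of either group. ISG15, an interferon-induced ubiquitin-like protein, reached 10.39 in CON 2, 9.39 in CON 7 and 9.28 in NOCON 4 against a median of 7.73, and MX1 reached 6.72 in CON 2, 6.46 in NOCON 4 and 6.42 in CON 6 against a median of 4.79. IFI6 (7.26), OAS1Y (6.598) and IFI27 (8.32) were also highest in CON 2. The acute phase gene SAA3 was at 10.09 in CON 5, with the next array, CON 2, at 7.46 and a median of 6.15. CON 5 also had the highest values of the muscle genes ACTC1 (7.76, next 6.06) and DES (8.61, next 7.58). The calcium-binding protein CALB1 was at 9.07 in CON 8, 7.81 in NOCON 3 and 6.89 in NOCON 1, against a median of 4.07.

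Among 18435 genes, 9 had values at separate levels with a gap of at least 1.5 on the log2 scale between the arrays of each level. The rarer level held 2 to 4 arrays, so the smallest p that Fisher's exact test can give for feeding is 0.0769, and the test decides nothing here. NDUFB8, a subunit of respiratory complex I, was at 6.43 in CON 2, 5.53 in CON 6 and 6.42 in NOCON 2, and between 9.21 and 10.29 in the other arrays. RBIS, a ribosome biogenesis factor, was at 5.36 in CON 1, 5.45 in CON 3, 6.15 in CON 5 and 5.18 in NOCON 4, and between 8.56 and 10.27 elsewhere. TSPAN6, a tetraspanin, was at 9.32 in CON 4, 8.99 in CON 7 and 9.19 in NOCON 7, and between 6.79 and 7.45 elsewhere. LOC100337129 was at 7.75 in CON 3, 7.18 in CON 4 and 5.90 in NOCON 5, and at most at 3.45 elsewhere. The remaining 5, the olfactory receptor genes OR11K5, OR6B9P and OR10K1C with LOC785105 and LOC780876, were high only in CON 2, CON 6 or CON 7, so all of their high arrays were CON.

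Random spread around a single level gave 0 such genes in simulated arrays, against 9. Low-correlation arrays held 64% of the places on the smaller side over the 9 genes, against 31.2% of the arrays, and for 5 genes they held all places. Part of the set is thus tied to those arrays, as low quality would give. Real differences between heifers would give the same. For RBIS alone, 0 of its 4 low arrays were low-correlation arrays, so array quality, as judged by correlation, does not account for that gene. No biological explanation was tested for RBIS, and no genotype was used here.

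The mitochondrial ribosomal protein genes MRPS18C and MRPL23 in the ranking led to a hypothesis that this family is lower in CON. Of 77 members, 73 had a mean below 0 in CON minus NOCON (median log2 difference -0.20) and 0 passed. Of 100 splits, 4 gave a camera p as small as the real one (3.02e-15 at the preset correlation, unadjusted; smallest other 3.24e-21), and 3 other splits went further. Because the family was picked from this same comparison, this count cannot exclude chance. With an estimated correlation of 0.365 the p was 0.0705, and without CON 7 the median was -0.14, with 62 of 77 below 0. Without the low-correlation arrays the camera p at the preset correlation was 0.00235 (unadjusted). A lower level of this family in CON therefore stays a candidate, not a finding.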
